A study of Mus musculus with 24 samples.

How the data were processed

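RNA sequencing was analysed from HY19636, a mouse pancreatic ductal adenocarcinoma (PDAC) cell line. Per the labels, the cells were wild type (WT) or knockout (KO) for Phgdh, were grown in medium with serine and glycine or free of both, and were grown alone (monoculture) or together with hepatocytes (coculture). The 3 factors were fully crossed, which made 8 groups of 3 libraries, 24 in all. Total RNA was extracted with a column kit and libraries were made by a commercial provider, per the labels' protocols. Reads were aligned with HISAT2 to the mouse genome GRCm38 (mm10), per the submitters' processing notes. The HISAT2 version, the read counter, the gene annotation release, the use of strand, the way the cancer cells were separated from the hepatocytes and the part of Phgdh that was edited are not given in the sources used here. The labels number the replicates without saying that they came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

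The authors deposited one table of FPKM (fragments per kilobase of gene, scaled to sequencing depth) for 54532 genes in 24 columns, with Ensembl identifiers, symbols, GRCm38 positions, gene lengths and biotypes. The table had 0 columns of other samples. The deposited FPKM multiplied by gene length were whole multiples of one step in each library (100% of values within 0.01 read), which gave back the reads per gene and totals of 15740081 to 23479425 reads per library. The total by which each library had been scaled was 0.969 to 1.068 times its own total, so a factor other than the plain library total had been applied, and which one is not given in the sources used here. Of the identifiers, 99.8% were found in the GENCODE vM21 annotation of GRCm38, and 98.3% had the same position there. Among the deposited symbols, 27 had been turned into dates and 207 gene names occurred more than once, so genes were followed by identifier. No pair of libraries was identical (0 pairs), and replicate libraries differed by more than sampling noise, with chi-square values per degree of freedom of 2.99 to 65.72 over genes with at least 20 reads.

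Genes at an FPKM of at least 1 in at least 3 libraries were kept (12061 genes) and tested as log2(FPKM + 1). All 24 libraries entered one model of 8 group means with 16 residual degrees of freedom and no replicate block, fitted with limma 3.58.1 (moderated test with a mean-variance trend, two-sided) in R 4.3.3. Adjusted p-values are Benjamini-Hochberg values over the 12061 genes of a comparison, and genes were called at an adjusted p under 0.05. There were 12 comparisons of 2 groups and 5 interactions, which test the difference between effects. Every log2 change is on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. Values after ± are standard errors for log2 changes and SDs over 3 libraries for FPKM. The response to serine and glycine withdrawal that was kept in coculture was described by the slope, through the origin, of the coculture change on the monoculture change over the genes called in monoculture; the libraries behind the axes were different ones.

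The lists numbered 24 and were fixed together with the tests, the model and the naming rule before the data were examined. They covered serine and one-carbon enzymes, ATF4 and the amino acid response, amino acid transporters, cytosolic aminoacyl-tRNA synthetases, chaperones of the endoplasmic reticulum (ER) and the unfolded protein response, DNA replication and S phase, mitosis, p53 targets, cholesterol synthesis, fatty acid synthesis and desaturation, hypoxia and glycolysis, NRF2 and glutathione, the interferon response, NF-kB and inflammatory mediators, epithelial genes, mesenchymal and TGF-beta response genes, mitochondrially encoded genes, cytosolic ribosomal proteins, and markers of hepatocytes, macrophages and Kupffer cells, endothelial cells, stellate cells and fibroblasts, cholangiocytes, and acinar and islet cells. The 19 lists with at least 3 tested members were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over 323 tests (19 lists by 17 comparisons). Camera with an estimated correlation and limma's fry were run beside it. Counts of list members past the threshold were taken over all tested genes and again adjusted over the list alone. Of 131 list calls, 79 were also called with an estimated correlation and 52 were not. fry, which asks whether a list moves on balance one way but not whether more than other genes, called 129 of the 131 and so adds little.

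The genes named in the text follow a rule. They are Phgdh everywhere. In each comparison of 2 groups they are the 6 largest rises and the 6 largest falls by log2 change among protein-coding genes with an adjusted p under 0.05, no overlap between the 3 and 3 libraries, a mean FPKM of at least 5 in the higher group, and a symbol that is not a predicted or clone name. Chance gives no overlap of 3 and 3 values for 10% of genes. In each interaction they are the 4 largest differences in each direction, without the condition on overlap. From each list described they are up to 4 members past the threshold with the largest change, and the member with the highest FPKM where fewer passed. Some genes that the rule names are not reported here. Gapdh, whose reads may be shared with near-identical copies, was left out. Reads of Prl2c2, Prl2c3, Prl2c5 and Klra4, which belong to gene families with near-identical copies, and of Rps28 are uncertain for the same reason. Without the strand setting, reads of overlapping genes on opposite strands cannot be told apart, which concerns, among others, Nr1d1 (1075 bases shared with Thra), Pclaf (13030 bases with Trip4), Plppr3 (4297 bases with Ptbp1), Rps28 (3892 bases with Kank3), Angptl8 (1838 bases with Dock6), Ccna2 (863 bases with Exosc9) and, over shorter stretches, Rnaseh2c (423 bases with Kat5), Ereg (152 bases with Gm19610), Atf5 (571 bases with Nup62), Leng8 (263 bases with Leng9), Igfbp7 (85 bases with Polr2b) and Cdc20 (53 bases with Elovl1). Plec shares 1401 bases with Parp10 on the same strand.

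The alternatives fixed in advance were median-of-ratios scaling, quantile normalization, a fit to the groups of the contrast alone, leaving out each library in turn, an estimated correlation for the lists, no filter on low values, limma voom on the recovered reads, the replicate number as a block, and a pseudocount of 0.1. Scaling to each library total, a correction for GC content and gene length (alone and with the replicate block), a restriction to protein-coding genes and 2 fits that each left out 2 KO libraries far from their groups were chosen after seeing the data. Libraries with the same replicate number deviated together only in the comparison of medium in KO monocultures, where the correlations of deviations from the group means were 0.4, 0.28 and 0.11 for the 3 numbers. There the fit with the replicate block called 8463 genes against 8534 without it, and 8883 with the block and the correction for GC content and length.

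Reads were simulated with the totals of the real libraries (11147 genes, dispersion 0.01, 200 changed genes). Gene means in every library were those of WT monocultures with serine and glycine, before the changes were put in. On these reads the test was run for the comparison of medium in KO monocultures. It called 8.9% of genes changed 1.25-fold, 57.4% of those changed 1.5-fold, 95.7% of those changed 2-fold and 100% of those changed 4-fold, all in the right direction, with 4 unchanged genes called. Smaller changes were thus often missed in the simulated reads. Their dispersion and number of changed genes were set, and the real comparison called far more genes (8534), so these shares need not hold there. Reads were recovered with 0 errors from simulated FPKM, but with the simulated totals given, which fixed that outcome. The search for the step, as done on the deposited values, was not tested this way. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.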

Results

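Transcripts were measured by RNA sequencing in the mouse PDAC line HY19636 in a design that crossed loss of Phgdh, withdrawal of serine and glycine from the medium, and coculture with hepatocytes. Phgdh encodes the first enzyme of serine synthesis from glucose. The title of the series concerns hepatocytes as a source of serine for pancreatic cancer cells in liver metastasis. Each of the 8 groups held 3 libraries, and every mean below is over n = 3 unless another number is given. Of the reads assigned to genes, 97.2 to 98.1% came from protein-coding genes and 1.81 to 2.92% from the mitochondrial genome. Pearson correlations between replicate libraries on the log2 scale were 0.9666 to 0.993, across genes. The lowest belonged to KO monocultures with serine and glycine, in which replicate 1 stood apart from the others. Replicate 1 of the serine- and glycine-free KO monocultures also differed more from replicates 2 and 3 (chi-square per degree of freedom 18.18 and 14.08) than these did from each other (3.21). In the serine- and glycine-free KO cocultures replicates 1 and 2 lay at opposite ends with replicate 3 between them (chi-square per degree of freedom 41.07 between 1 and 2, 15.48 between 1 and 3, and 13.82 between 2 and 3). The first 3 principal components held 43.2%, 23.9% and 11.2% of the variance. List counts adjusted over the list alone were equal to those over all genes unless both are given. A list called by camera with one p was also called with an estimated correlation, and a second p is given where it was not.

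Phgdh transcript was lower in KO than in WT cells but was far from absent. Phgdh (ENSMUSG00000053398, chromosome 3, 98313170 to 98339990, GRCm38) had an FPKM of 922 ± 16.6 (SD, n = 3) in WT and 483 ± 96.6 in KO monocultures with serine and glycine. The log2 change was −0.95 ± 0.12 (limma adjusted p = 1.85e-06). It was also lower in KO cells in coculture with serine and glycine (1300 ± 55.2 in WT, 874 ± 9.34 in KO, −0.57, adjusted p = 0.000504). Without them it was again lower (1310 ± 83 in WT, 716 ± 106 in KO, −0.88, adjusted p = 3.13e-06). In serine- and glycine-free monocultures the FPKM was 800 ± 15.5 in WT and 695 ± 68.6 in KO, which did not pass the test (−0.21, adjusted p = 0.115). That value was −0.29 with limma voom on the recovered reads, which called it, and 0.19 with quantile normalization, which did not. Its adjusted p ranged from 0.00593 to 0.511 over the alternatives. Phgdh rose on withdrawal in KO monocultures (0.54, adjusted p = 0.000371). Its change on withdrawal was −0.30 in KO coculture (adjusted p = 0.0594, and 0.000421 to 0.315 over the alternatives), −0.20 in WT monoculture (adjusted p = 0.536, and 0.0286 to 0.884 over the alternatives) and 0.01 in WT coculture (adjusted p = 0.999), none of which passed the test as reported. It rose in coculture in WT cells (0.49 with serine and glycine, adjusted p = 0.00272, and 0.71 without, adjusted p = 9.44e-05) and in KO cells with serine and glycine (0.88, adjusted p = 5.86e-06). In serine- and glycine-free KO cells the coculture change was 0.04 (adjusted p = 0.788) and turned to −0.41 with quantile normalization (adjusted p = 0.000358). The gene total thus separated the genotypes by label in 3 of 4 conditions. It does not test whether functional enzyme was lost, because transcripts from an edited gene can still be sequenced and the edited part is not given in the sources used here.

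**Figure D1:**
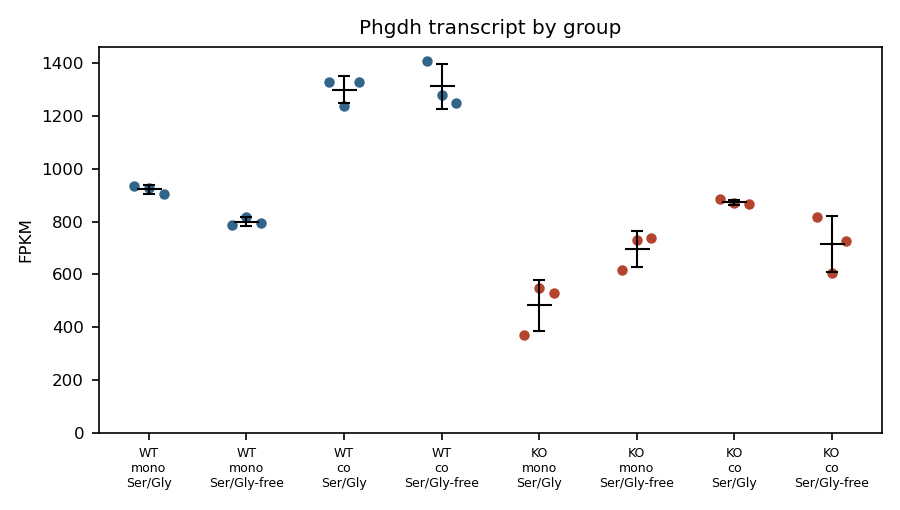
Phgdh expression in FPKM (vertical axis, from 0) in each library (points) of the 8 groups, with the mean and SD over 3 libraries. KO groups lay between 483 and 874 on average and WT groups between 800 and 1310.

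Comparison of KO with WT cells asked what differed between the genotypes in each culture condition. In monoculture with serine and glycine, the largest rises in KO cells were in Prl2c3 (ENSMUSG00000056457, chromosome 13, 12790816 to 12800079), a prolactin family member (4.41 ± 0.14, adjusted p = 7e-15). Its FPKM was 6.61 ± 1.33 in WT and 161 ± 26.1 in KO cells. It was followed by the adhesion gene Cdh17 (2.95 ± 0.08), the sodium-proton exchanger Slc9a2 (2.87 ± 0.08), Prl2c2 (2.77 ± 0.21), Pawr (2.71 ± 0.16), and the atypical protein kinase C gene Prkcz (2.67 ± 0.07). Serpinh1 (ENSMUSG00000070436, chromosome 7, 99345376 to 99353239), the collagen chaperone HSP47, had an FPKM of 13.3 to 15.2 in the 12 WT libraries in contrast to 1 read over the 12 KO libraries, 11 of which had 0. The other large falls were in the cornified envelope gene Sprr1a (−3.61 ± 0.06), the apolipoprotein Apob (−3.44 ± 0.09), Igfbp7 (−3.15 ± 0.11), the cytokine receptor Crlf2 (−3.14 ± 0.16) and the matrix gene Fbln2 (−2.89 ± 0.11). Of 23 tested NRF2 and glutathione genes 14 rose and 2 fell (median 0.23, camera adjusted p = 5.12e-05). They were led by the cystine transporter Slc7a11 (1.38 ± 0.09), Srxn1 (1.21), the ferritin chain Fth1 (1.04) and Gstm1 (0.98). Of 16 amino acid transporters 9 rose and 2 fell (median 0.30, adjusted p = 0.00302, but adjusted p = 0.0758 with an estimated correlation). Among them were Slc3a2 (1.16), Slc7a1 (0.82) and Slc1a4 (0.64). Of 29 hypoxia and glycolysis genes 15 rose and 4 fell (16 and 4 adjusted over the list alone; adjusted p = 0.00182, and adjusted p = 0.117 with an estimated correlation). Of 28 mitosis genes 1 rose and 9 fell (adjusted p = 0.00475, and adjusted p = 0.16 with an estimated correlation). Cdk1 was at −0.91 and Top2a at −0.81. Epithelial genes rose in 7 cases and fell in 3 (10 and 3 adjusted over the list alone) of 15, with Krt19 at 1.45 and Muc1 at −1.57 (adjusted p = 0.0382, and adjusted p = 0.203 with an estimated correlation). Fatty acid synthesis genes rose in 9 and fell in 3 of 15 (adjusted p = 0.0396, and adjusted p = 0.0733 with an estimated correlation). Of the 23 serine and one-carbon enzymes 11 rose and 6 fell, with the glycine cleavage gene Gldc at 1.17 and Aldh1l2 at 0.47. The list did not pass (adjusted p = 0.165). In all, 5145 of 12061 genes (42.7%) were called, 2596 higher and 2549 lower in KO cells. Of these, 194 and 226 changed at least 2-fold. With only the 2 groups of the contrast in the fit, 3165 genes were called.

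Many of the same differences recurred in coculture. With serine and glycine, KO cells had higher Prl2c3 (4.42 ± 0.14), Prl2c2 (3.80 ± 0.21), Pawr (3.29 ± 0.16), the transcription factor Zic2 (3.15 ± 0.12), N-cadherin Cdh2 (2.64 ± 0.09) and Prl2c5 (2.62 ± 0.12). Apob was lower (−4.74 ± 0.09), at an FPKM of 68.6 ± 3.28 in WT and 1.61 ± 0.162 in KO cells. So were Aplp1 (−3.44 ± 0.07), the ligand gene Wnt7a (−3.03 ± 0.07), Igfbp7 (−2.94 ± 0.11) and Crlf2 (−2.84 ± 0.16), beside Serpinh1. In serine- and glycine-free coculture the rises were led by Prl2c3 (5.06 ± 0.14), Prl2c2 (4.06 ± 0.21), Csn3 (3.26 ± 0.07), Pgap1 (3.26 ± 0.11), Slc9a2 (3.21 ± 0.08) and the aldo-keto reductase Akr1b7 (3.17 ± 0.16). The falls there were led by Wnt7a (−4.31 ± 0.07), Apob (−4.29 ± 0.09), Igfbp7 (−3.49 ± 0.11), Aplp1 (−3.27 ± 0.07) and thrombomodulin Thbd (−3.05 ± 0.10), beside Serpinh1. NRF2 and glutathione genes rose in 17 and fell in 2 of 23 cases with serine and glycine (median 0.30, camera adjusted p = 1.38e-05). Without them 15 rose and 2 fell (median 0.29, adjusted p = 0.000385), and Slc7a11 reached 2.32 ± 0.09 and Gss, a glutathione synthesis enzyme, 0.98. Amino acid transporters rose in 10 and fell in 2 of 16 with serine and glycine (adjusted p = 0.00258, and adjusted p = 0.0733 with an estimated correlation). Without them 8 rose and 3 fell (adjusted p = 0.0342, and adjusted p = 0.2 with an estimated correlation). Cholesterol synthesis genes rose in 10 and fell in 3 of 25 with serine and glycine (median 0.22, adjusted p = 0.0299). Cyp51 was at 0.54, Insig1 at 0.51 and Nsdhl at −0.74. The list's call was lost with quantile normalization (adjusted p = 0.0928). Mitosis genes fell in 12 and rose in 2 of 28 with serine and glycine (adjusted p = 0.0223, and adjusted p = 0.233 with an estimated correlation). Without them 17 rose and 1 fell (20 and 2 adjusted over the list alone; adjusted p = 0.00767, and adjusted p = 0.181 with an estimated correlation). Among the serine- and glycine-free KO cocultures replicates 1 and 2 lay at opposite ends of their group. In that comparison cytosolic ribosomal protein genes fell in 20 and rose in 3 of 37 (22 and 4 adjusted over the list alone; adjusted p = 0.0109, and adjusted p = 0.418 with an estimated correlation). Mitochondrially encoded genes rose in 7 of 13 (adjusted p = 0.0117, and adjusted p = 0.39 with an estimated correlation). The numbers of called genes were 5291 with serine and glycine (2635 higher, 2656 lower) and 6470 without (3167 higher, 3303 lower). Across all 4 conditions 1914 genes were called with one sign, 926 higher and 988 lower in KO cells. Of these, 61 and 101 differed at least 2-fold in each.

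The genotypes lay farthest apart in monocultures free of serine and glycine. There KO cells had higher Dynap (5.99 ± 0.10; ENSMUSG00000024512, chromosome 18, 70240429 to 70244584). Also higher were the epidermal growth factor receptor ligands Ereg (5.25 ± 0.13) and Areg (4.77 ± 0.16), the circadian repressor Nr1d1 (5.10 ± 0.10), Fam84a (4.84 ± 0.08) and Pawr (4.34 ± 0.16). Igfbp7 was lower (−7.21 ± 0.11), at an FPKM of 293 ± 5.6 in WT and 1 ± 0.326 in KO cells. The mucin Muc1 (−5.22 ± 0.06) was at 69 ± 1.19 in WT and 0.882 ± 0.156 in KO cells. Further falls were in Serpinb6b (−5.22 ± 0.12), Wnt7a (−4.92 ± 0.07), the desaturase Scd2 (−4.89 ± 0.07) and Apob (−4.83 ± 0.09). DNA replication and S phase genes were higher in 36 of 37 cases and lower in 0 (median 1.32, camera adjusted p = 1.26e-11). The ribonucleotide reductase gene Rrm2 was at 4.13 ± 0.12, the helicase subunit Mcm5 at 2.64 and Cdc6 at 2.54. Mitosis genes were higher in 26 of 28 (median 1.07, adjusted p = 6.33e-08). They included Ccna2 (2.69), Top2a (2.61) and Mki67 (2.38). All 25 cholesterol synthesis genes were lower (median −1.77, adjusted p = 2.31e-11). They included Nsdhl (−3.41) and Stard4 (−2.79). Fatty acid synthesis genes were lower in 12 and higher in 2 of 15 (adjusted p = 0.000277). ER chaperone genes were lower in 19 of 20 (median −0.49, adjusted p = 3.36e-05). Hypoxia and glycolysis genes were lower in 22 and higher in 5 of 29 (median −0.72, adjusted p = 9.89e-05, but adjusted p = 0.0523 with an estimated correlation). Among them were Bnip3 (−3.54), Eno1 (−2.27), Aldoc (−2.19) and Egln3 (−2.10). Ribosomal protein genes were lower in 32 of 37 (median −0.72, adjusted p = 5.31e-07, but adjusted p = 0.128 with an estimated correlation). Aminoacyl-tRNA synthetases were higher in 14 and lower in 4 of 20 (adjusted p = 0.0166, but adjusted p = 0.171 with an estimated correlation and 0.274 with quantile normalization). Serine and one-carbon enzymes went both ways, 14 higher and 8 lower (adjusted p = 0.193). Mtr was at 1.34, Tyms at 1.30 and Shmt2 at −1.39. In total 8880 genes (73.6%) were called, 4506 higher and 4374 lower. Of these, 1344 and 1492 differed at least 2-fold.

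Withdrawal of serine and glycine asked how far each genotype depended on their supply. In WT monocultures the laminin chain Lama5 (ENSMUSG00000015647, chromosome 2, 180176373 to 180225859) rose by 0.64 ± 0.13 (adjusted p = 0.015). The other leading rises were in the atypical cadherin Fat1 (0.60 ± 0.07, adjusted p = 6.66e-05), the basement membrane gene Hspg2 (0.56 ± 0.12), the cytolinker Plec (0.53 ± 0.10), Fosb (0.52 ± 0.13) and the histone methyltransferase Kmt2d (0.52 ± 0.12). The falls were led by Cdh17 (−0.48 ± 0.08, adjusted p = 0.00225), Tspan12 (−0.45 ± 0.09), the spliceosome gene Snrpf (−0.36 ± 0.07), the growth factor Pgf (−0.34 ± 0.08), Car6 (−0.33 ± 0.07) and Add2 (−0.33 ± 0.07). Of these 12 genes only Fat1, Plec and Cdh17 kept their call in every alternative run, leaving out single libraries included. Kmt2d, for one, was at 0.18 (adjusted p = 0.259, the highest over its alternatives, from 0.0294 as reported) after correction for GC content and length. Serine and one-carbon enzymes had 1 call of 23, a fall in Cth (−0.22), and did not pass as a list (adjusted p = 0.196). ATF4 and amino acid response genes had 1 fall of 30 (adjusted p = 0.737). Of 21 mesenchymal genes 2 rose and 1 fell (3 and 1 adjusted over the list alone; median 0.11, camera adjusted p = 0.0074). Fibronectin Fn1 was at 0.31, Cyr61 at 0.25 and Vim at −0.24. Other lists passed at the preset correlation with small shifts but not with an estimated one. Amino acid transporters had a median of 0.06 and 1 rise, in Slc7a1 (0.19), or 4 adjusted over the list alone (adjusted p = 0.0909 with an estimated correlation). Epithelial genes had a median of 0.09 and 2 rises, in Cdh1 (0.33) and Dsp (0.39) (adjusted p = 0.0757 with an estimated correlation). Fatty acid synthesis genes had a median of 0.04 and 1 rise, in Fasn (0.45), or 2 adjusted over the list alone (adjusted p = 0.0824 with an estimated correlation). S phase genes had a median of −0.07 with 0 members called and 1 fall adjusted over the list alone (adjusted p = 0.0733 with an estimated correlation). Ribosomal protein genes had a median of −0.11 with 0 members called (adjusted p = 0.142 with an estimated correlation, and 0.577 with quantile normalization). Mitochondrially encoded genes had a median of −0.24 with 0 members called (adjusted p = 0.181 with an estimated correlation). In all 196 genes (1.6%) were called, 165 higher and 31 lower, with 1430 at an unadjusted p under 0.05. The count was 302 with only the 2 groups in the fit. It was 62 without replicate 3 of the serine- and glycine-free WT monocultures, and leaving out any one of the 6 libraries gave at most 140. It rose to 518 and 525 in the 2 fits that each left out 2 KO libraries far from their groups, and was 130 with the replicate block and the correction for GC content and length.

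Cell cycle genes led the response of WT cocultures. On withdrawal Ect2 (ENSMUSG00000027699, chromosome 3, 27097222 to 27153878), needed for cytokinesis, rose by 0.79 ± 0.12 (FPKM 3.46 ± 0.442 to 6.71 ± 0.464, adjusted p = 0.00311). Rrm2 (0.68 ± 0.12), the replication helicase subunits Mcm5 (0.61 ± 0.09) and Mcm3 (0.55 ± 0.07), the mitotic activator Cdc20 (0.57 ± 0.12) and the transporter Slco4a1 (0.54 ± 0.08) rose too. The falls were in Apoe (−0.72 ± 0.15, adjusted p = 0.0221), Atg9b (−0.57 ± 0.08), Casc1 (−0.51 ± 0.05), Tmem267 (−0.49 ± 0.09), Paxbp1 (−0.36 ± 0.07) and Stbd1 (−0.36 ± 0.08). Of 37 S phase genes 9 rose (23 adjusted over the list alone; median 0.25, camera adjusted p = 1.29e-27). Of 28 mitosis genes 6 rose (23 adjusted over the list alone; median 0.36, adjusted p = 1.41e-27). Bub1 was at 0.58, Top2a at 0.57 and Ccnb1 at 0.54. Cholangiocyte markers rose in 1 of 7 cases (2 adjusted over the list alone), in Anxa13 (0.47; adjusted p = 0.00033). Cholesterol synthesis genes (median −0.05, adjusted p = 0.023) and NRF2 genes (median 0.07, adjusted p = 0.0198) passed as lists with 0 members called. The first call was lost without replicate 1 (adjusted p = 0.053) or replicate 3 (adjusted p = 0.0854) of the libraries with serine and glycine, and the second without replicate 1 of those free of both (adjusted p = 0.0571). Hypoxia genes (median −0.06, adjusted p = 0.139 with an estimated correlation) and mitochondrially encoded genes (median −0.18, adjusted p = 0.359 with an estimated correlation) passed only at the preset correlation. The number of called genes was 89 (53 higher, 36 lower), with 1143 at an unadjusted p under 0.05. With only these 2 groups in the fit 4 genes were called, and all 12 genes named here lost their call. Without replicate 1 of the WT cocultures with serine and glycine the count was 37, and with a pseudocount of 0.1 it was 59. It was higher with the correction for GC content and length (219, and 198 with the replicate block too) and in the 2 fits without KO libraries far from their groups (241 and 232).

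In KO monocultures the same withdrawal changed most of the transcriptome. Sprr1a (ENSMUSG00000050359, chromosome 3, 92483952 to 92485895) rose from an FPKM of 12.5 ± 0.81 to 882 ± 41 (log2 change 6.03 ± 0.06, adjusted p = 2.21e-23). Nr1d1 (ENSMUSG00000020889, chromosome 11, 98767932 to 98775333) rose from 3.16 ± 0.199 to 140 ± 14.8 (5.07 ± 0.10) and Dynap from 4.37 ± 0.745 to 150 ± 8.42 (4.83 ± 0.10). Ereg (ENSMUSG00000029377, chromosome 5, 91074622 to 91093646) went from 6.42 ± 1.6 to 156 ± 14.4 (4.43 ± 0.13) and Rrm2 (ENSMUSG00000020649, chromosome 12, 24708241 to 24714146) from 1.48 ± 0.44 to 51.9 ± 4.46 (4.42 ± 0.12). The collagenase Mmp13 rose from 6.63 ± 1.4 to 155 ± 15.9 (4.36 ± 0.12). Scd2 (ENSMUSG00000025203, chromosome 19, 44293676 to 44306864) fell from 631 ± 70.9 to 13.5 ± 0.472 (−5.44 ± 0.07, adjusted p = 1.07e-21). The galectin Lgals4 fell from 136 ± 31.4 to 2.63 ± 0.568 (−5.22 ± 0.14). Next came Igfbp7 (−4.08 ± 0.11), Gstm1 (−4.01 ± 0.11), the desaturase Fads2 (−4.01 ± 0.09) and Slco4a1 (−3.91 ± 0.08). A total of 8534 genes (70.8%) were called, 4372 higher and 4162 lower. Of these, 1099 and 1157 changed at least 2-fold.

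**Figure D2:**
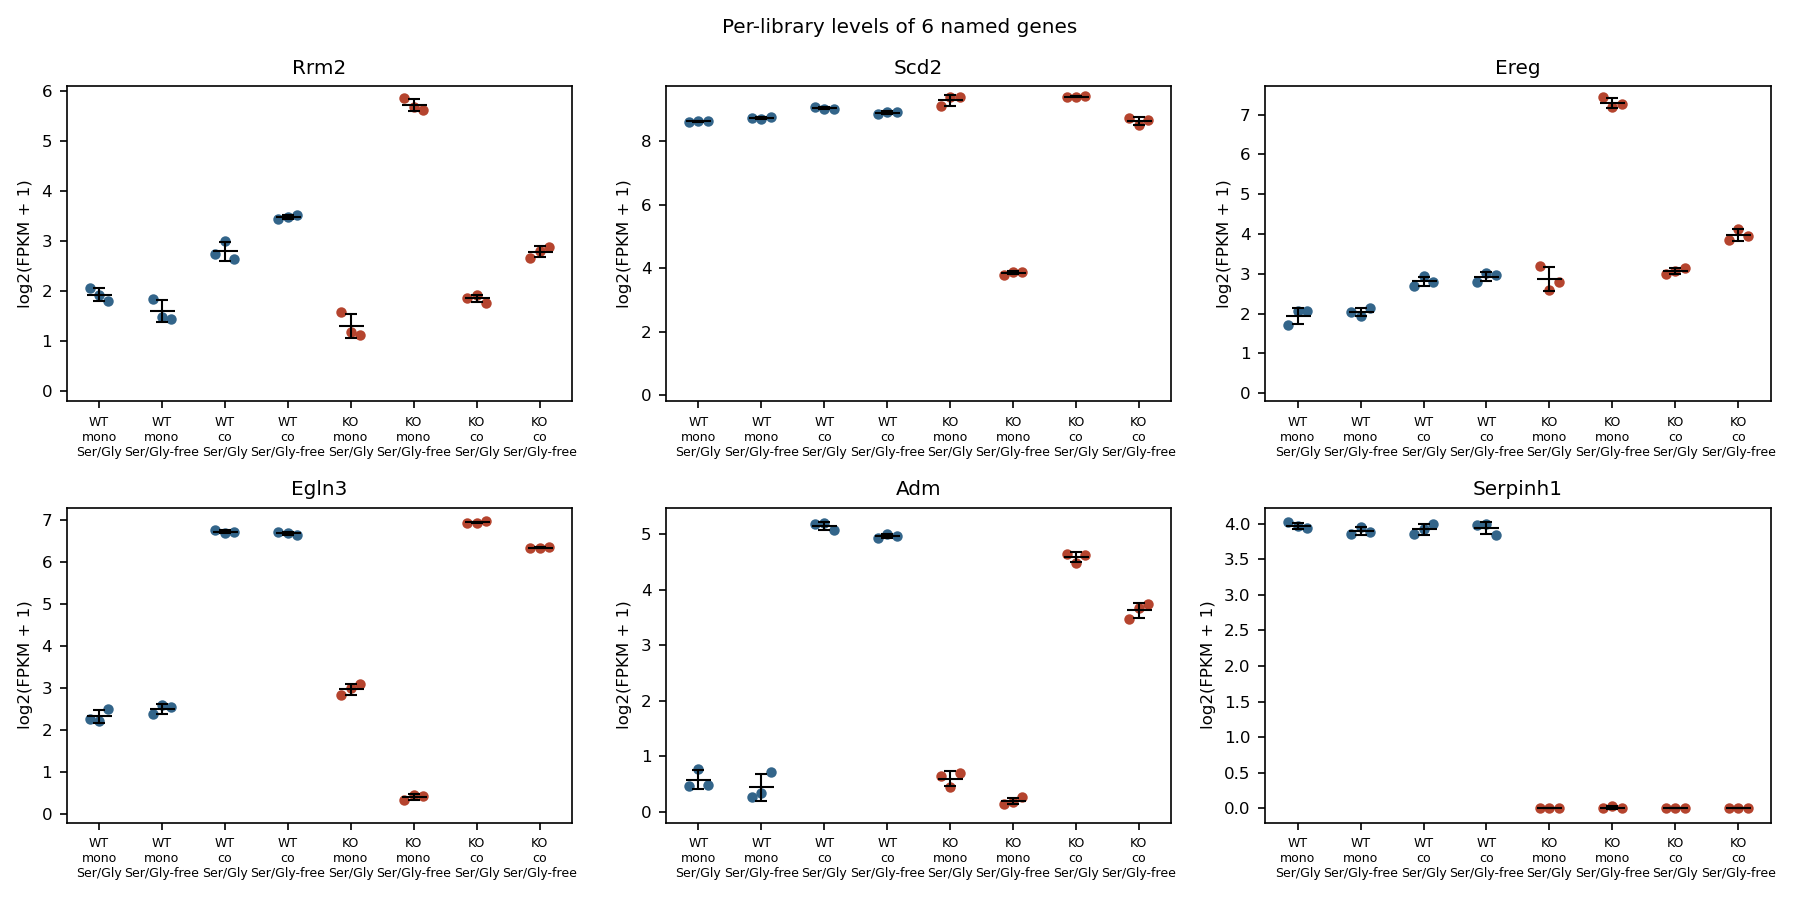
Expression as log2(FPKM + 1) (vertical axis) of Rrm2, Scd2, Ereg, Egln3, Adm and Serpinh1 in each library (points) of the 8 groups, with mean and SD over 3 libraries. Serine- and glycine-free KO monocultures stand apart from the other 7 groups in Rrm2, Scd2 and Ereg, cocultures from monocultures in Egln3 and Adm, and KO from WT in Serpinh1.

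Most members of several gene lists moved one way in these cells, while other lists split. All 37 S phase genes rose (median 1.20, camera adjusted p = 1.28e-13). They included Mcm5 (3.56), Cdc6 (2.95) and Mcm3 (2.81). Of 28 mitosis genes 27 rose (28 adjusted over the list alone; median 1.43, adjusted p = 2.59e-10). They included Top2a (3.4), Ccna2 (2.95), Mki67 (2.61) and Kif11 (2.16). All 25 cholesterol synthesis genes fell (median −1.64, adjusted p = 7.19e-13). They included Idi1 (−2.65) and Insig1 (−2.57). Of 15 fatty acid synthesis genes 13 fell and 2 rose (median −0.94, adjusted p = 4.29e-05). Scd1 was at −2.89 and Fads1 at −2.19. Hypoxia and glycolysis genes fell in 23 and rose in 3 of 29 (median −1.14, adjusted p = 1.18e-07). Bnip3 was at −3.28, Aldoc at −2.97 and Pdk1 at −2.68. ER chaperone and unfolded protein response genes fell in 19 of 20 (median −0.71, adjusted p = 3.79e-07). Sdf2l1 was at −2.03 and Edem1 at −1.76. NRF2 genes fell in 16 and rose in 6 of 23 (median −0.33, adjusted p = 0.00876). Slc7a11 was at −2.43, Pgd at −2.12 and Fth1 at −2.07. Ribosomal protein genes fell in 29 of 37 (median −0.71, adjusted p = 1.89e-08, but adjusted p = 0.0839 with an estimated correlation). Aminoacyl-tRNA synthetases rose in 13 and fell in 3 of 20 (13 and 4 adjusted over the list alone; adjusted p = 0.0175, but adjusted p = 0.174 with an estimated correlation and 0.127 with quantile normalization), with Aars and Lars at 1.27, Yars at 1.19 and Qars at −1.83. ATF4 and amino acid response genes split, 14 up and 11 down of 30 (adjusted p = 0.965). The transcription factor Atf5 was at 1.97, Slc3a2 at −1.96 and Pck2 at −1.82. Serine and one-carbon enzymes split too, 13 up and 8 down of 23 (adjusted p = 0.407). Shmt1 was at 1.28, Shmt2 at −1.62 and Amt at −1.30.

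**Figure D3:**
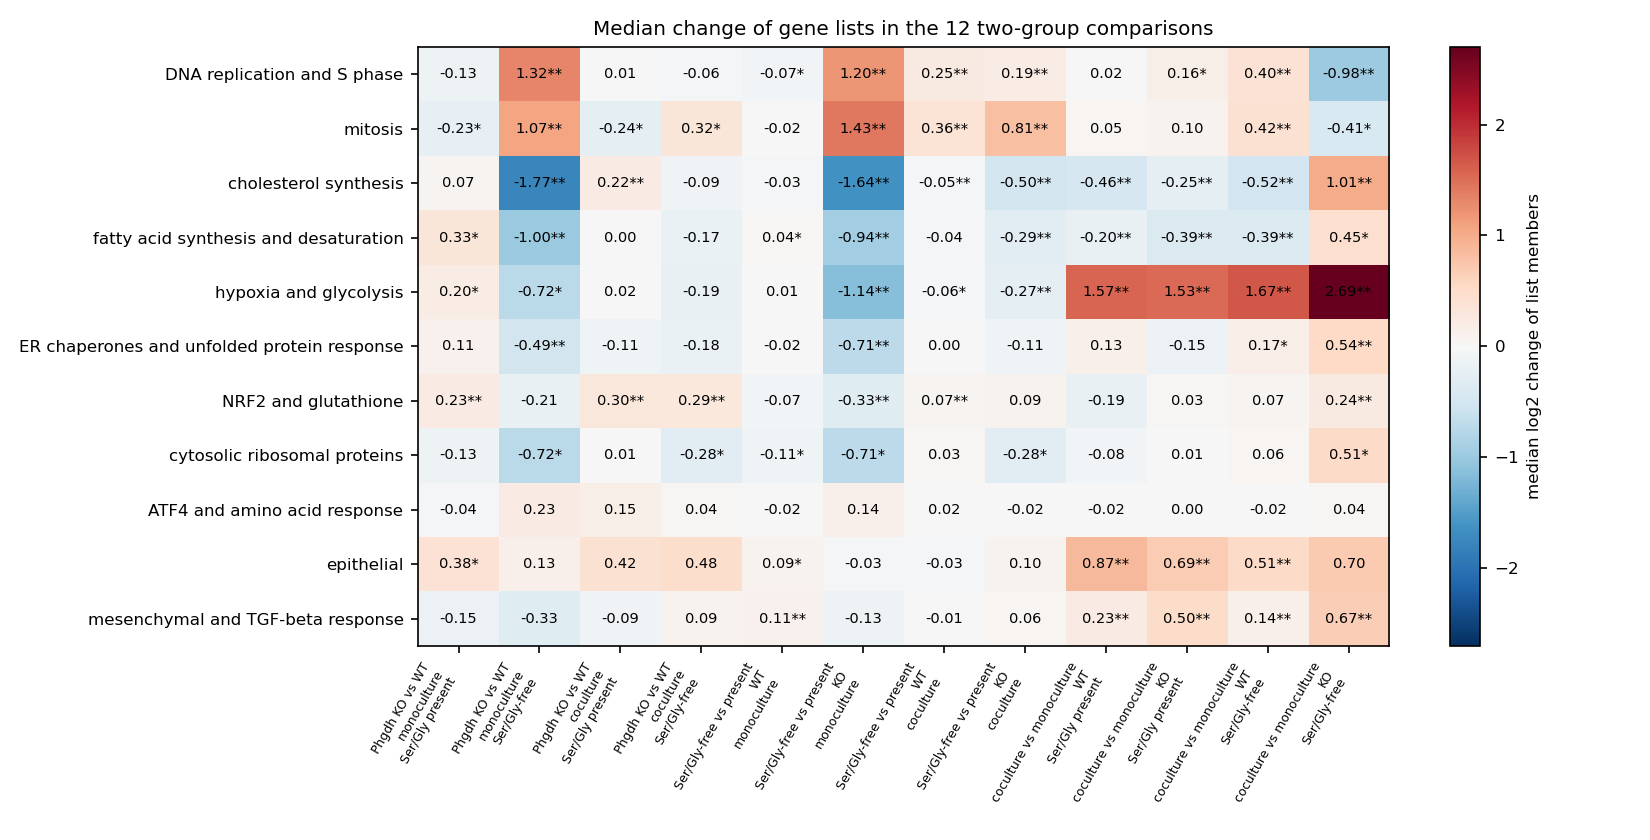
Median log2 change (colour) of 11 gene lists (vertical) in the 12 comparisons of 2 groups (horizontal); 1 asterisk marks a camera adjusted p under 0.05 at the preset correlation, and a pair of asterisks marks lists called with an estimated correlation too. S phase and mitosis genes are highest, and cholesterol synthesis genes lowest, in the comparisons of serine- and glycine-free KO monocultures with WT cells and with KO cells given both amino acids (medians 1.32, 1.07 and −1.77, and 1.20, 1.43 and −1.64).

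KO cells in coculture responded to withdrawal with fewer and smaller changes. The largest rise was in involucrin, Ivl (ENSMUSG00000049128, chromosome 3, 92570902 to 92573735), from an FPKM of 3.42 ± 0.355 to 24.7 ± 3 (2.54 ± 0.11, adjusted p = 8.19e-12). Next were Mmp13 (2.08 ± 0.12), Klra4 (2.07 ± 0.17), the interleukin-1 receptor antagonist Il1rn (2.06 ± 0.08), the claudin Cldn2 (1.89 ± 0.09) and Gimd1 (1.79 ± 0.18). The falls were led by Lgals4 (−2.02 ± 0.14, adjusted p = 1.03e-08), Rnaseh2c (−1.39 ± 0.35), Trappc6a (−1.28 ± 0.34), Rps28 (−1.22 ± 0.38), the mevalonate pathway enzyme Pmvk (−1.22 ± 0.11) and Tmsb10 (−1.21 ± 0.32). All 28 mitosis genes rose (median 0.81, camera adjusted p = 3.45e-23). Ccnb1 was at 1.51, Kif11 at 1.36 and Tpx2 at 1.30. S phase genes rose in 14 and fell in 1 of 37 (17 and 2 adjusted over the list alone; median 0.19, adjusted p = 0.00034). Rrm2 was at 0.93 and Cdc6 at 0.90. Cholesterol synthesis genes fell in 18 of 25 (median −0.50, adjusted p = 5.61e-12). Mvd was at −1.14. Fatty acid synthesis genes fell in 9 of 15 (median −0.29, adjusted p = 4.33e-05). Fads2 was at −1.14 and Scd2 at −0.77. Hypoxia genes fell in 19 of 29 (24 adjusted over the list alone; median −0.27, adjusted p = 1.29e-10). Adm was at −0.96, Slc16a3 at −0.84 and Egln3 at −0.60. Cholangiocyte markers rose in 5 and fell in 1 of 7, with osteopontin Spp1 at 0.85 and Sox9 at 0.81 (adjusted p = 0.00507, but 0.052 among protein-coding genes alone). Ribosomal protein genes fell in 16 of 37 (22 and 1 risen adjusted over the list alone; adjusted p = 6.8e-06, but adjusted p = 0.175 with an estimated correlation and 0.127 with quantile normalization). Mitochondrially encoded genes rose in 6 of 13 (adjusted p = 0.000137, but adjusted p = 0.205 with an estimated correlation). mt-Nd4l was at 1.24 and mt-Cytb at 1.05. Serine and one-carbon enzymes rose in 5 and fell in 5 (8 and 6 adjusted over the list alone; adjusted p = 0.837). ATF4 genes rose in 5 and fell in 11 of 30 (6 and 12 adjusted over the list alone; adjusted p = 0.47). The number of called genes was 3607 (1865 higher, 1742 lower; 70 and 53 at least 2-fold). It was 1820 with only the 2 groups in the fit. Replicates 1 and 2 of the serine- and glycine-free KO cocultures lay at opposite ends of their group, and the number was 4619 without replicate 1 and 2152 without replicate 2. Without replicate 1 and without replicate 1 of the KO monocultures with serine and glycine it was 5763. Without replicate 2 Rps28 (−0.85), Tmsb10 (−0.93) and Trappc6a (−0.87) also lost their calls.

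Interactions tested whether coculture altered the response to withdrawal. In KO cells 6962 genes differed in their response between coculture and monoculture (3365 higher and 3597 lower in coculture). Scd2 (4.68 ± 0.09), the pantetheinase Vnn1 (4.48 ± 0.18) and Gstm1 (4.46 ± 0.15) had the largest positive differences. Sprr1a (−4.69 ± 0.08), Nr1d1 (−4.03 ± 0.15), Ereg (−3.52 ± 0.18) and Rrm2 (−3.49 ± 0.17) had the largest negative ones. S phase genes responded less positively in coculture in 37 of 37 cases (median −1.13) and cholesterol synthesis genes less negatively in 24 of 25 (median 1.05), both called with an estimated correlation. Mitosis genes, lower in 17 of 28 (median −0.58), were called only at the preset correlation (adjusted p = 0.0791 with an estimated correlation). Over the 8534 genes called in KO monoculture, the slope of the coculture change on the monoculture change was 0.136 (jackknife SE 0.042). Across these genes, which are not independent replicates, 65.5% had the same sign. Of those called in both, 2215 went the same way and 697 the opposite way. In WT cells the slope was −0.14 (SE 0.127) over 196 genes, about the size of its error, and it ran from −0.27 to 0.018 over the alternatives. In WT cells 201 genes differed in their response, with Rrm2 (1.02 ± 0.17) and Mcm3 (0.67) more positive and Apoe (−1.28 ± 0.21) and Fat1 (−0.75) more negative in coculture. That count ran from 100 to 552 over the alternatives. The interaction of genotype and medium in monoculture called 7385 genes, that of genotype and coculture without serine and glycine 7343, and that of all 3 factors 5605. In the last, Scd2 (4.93 ± 0.13) and Rrm2 (−4.51) were among the largest differences. All interactions but that in WT cells share the serine- and glycine-free KO monocultures, so genes that recur across interactions are not separate results. These libraries lay at 76.5 to 80.8 on the first component, the others at most at 13.2.

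**Figure D4:**
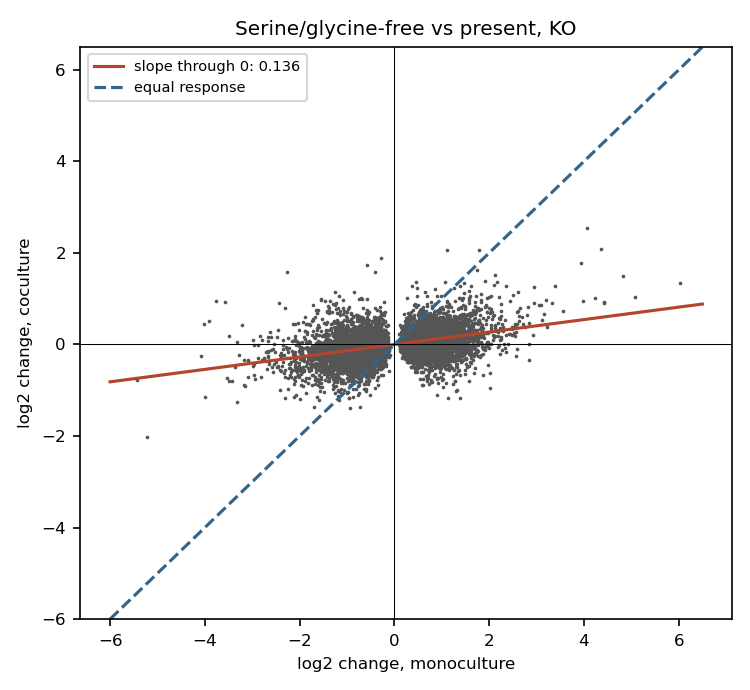
Log2 change on serine and glycine withdrawal in KO cells in monoculture (horizontal) and in coculture (vertical) for the 8534 genes called in monoculture, one point each. The red line is the slope through the origin, 0.136, and the dashed blue line is an equal response in both cultures.

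Coculture was compared with monoculture to ask what hepatocytes changed in the cancer cells. In WT cells with serine and glycine the largest rises were in 2 hypoxia-inducible genes. Adm (ENSMUSG00000030790, chromosome 7, 110627661 to 110629820), which encodes adrenomedullin, rose from an FPKM of 0.493 ± 0.181 to 34.7 ± 1.77 (4.58 ± 0.11, adjusted p = 3.32e-17). Egln3 (ENSMUSG00000035105, chromosome 12, 54178981 to 54203860), a prolyl hydroxylase, rose from 4.03 ± 0.52 to 104 ± 2.59 (4.39 ± 0.07). Also higher were Selenbp1 (3.56 ± 0.14), Cyp2s1 (3.51 ± 0.06) and the lysyl oxidase family member Loxl2 (3.38 ± 0.10). The falls were in the trypsinogen gene Try5 (−2.30 ± 0.20), the chemokine Ccl20 (−1.82 ± 0.21), Slco4a1 (−1.58 ± 0.08), Tmem158 (−1.55 ± 0.32), Itih2 (−1.46 ± 0.11) and Depp1 (−1.43 ± 0.17). Hypoxia and glycolysis genes rose in 27 of 29 cases (median 1.57, camera adjusted p = 1.43e-39). Bnip3 was at 3.17 and P4ha2 at 2.92. Cholesterol synthesis genes fell in 21 of 25 (22 adjusted over the list alone; median −0.46, adjusted p = 6.86e-10). Insig1 was at −0.95 and Idi1 at −0.86. Fatty acid synthesis genes fell in 7 and rose in 3 of 15 (8 and 3 adjusted over the list alone; median −0.20, adjusted p = 0.00984). Elovl6 was at −0.92, Scd1 at −0.86 and Me1 at 1.13. Epithelial genes rose in 10 and fell in 2 of 15 (median 0.87, adjusted p = 6.8e-06). Krt19 was at 3.36, Lamb3 at 1.96 and Itgb4 at 1.13. Mesenchymal and TGF-beta response genes rose in 10 of 21 (11 and 1 fallen adjusted over the list alone; median 0.23, adjusted p = 0.000201). They included Loxl2 and Fn1 (1.68). A total of 3763 genes were called, 1969 higher and 1794 lower. The higher calls were 52.3% of these, against 35.8% with scaling to each library total and 35.7% with limma voom on the recovered reads. At the reported scaling 313 of the higher and 44 of the lower genes changed at least 2-fold.

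Hepatocyte transcripts were scarce in all cocultures. Albumin, Alb, reached at most 0.131 FPKM in a coculture library and 0.0243 in a monoculture library, with 7 reads over all 12 cocultures and 3 over all 12 monocultures. Ttr was at most 0.183 in a coculture library (8 reads over all cocultures) and 0 in monocultures. Apoa1 was at most 0.0494 in a coculture library and 0.126 in a monoculture library, with 2 reads over all cocultures and 4 over all monocultures, and Fgb and Serpina1b were at 0. Of 33 hepatocyte markers 2 passed the expression filter, Apob and Rbp4. Both were expressed in monocultures. Rbp4 was at 145 FPKM in WT cells with serine and glycine and 62.7 in their coculture. Apob rose in coculture of WT cells from 34.1 ± 0.437 to 68.6 ± 3.28 with serine and glycine and from 39.6 ± 3.87 to 68.7 ± 4.38 without them. In KO cells it fell from 2.26 ± 0.453 to 1.61 ± 0.162 with them and rose from 0.423 ± 0.0234 to 2.56 ± 0.351 without. Of 18 macrophage and Kupffer cell markers 2 passed, Cd68 (8.74 in WT monoculture and 8 in coculture with serine and glycine) and Cd14 (17.9 and 6.33). Of 14 endothelial markers 1 passed, Egfl7 (0.761 and 1.41). The endothelial cadherin Cdh5, which did not pass the filter and was not tested, was at 0.415 ± 0.161 in KO monocultures and 1.21 ± 0.193 in KO cocultures with serine and glycine, and at 0.00994 ± 0.0172 and 0.859 ± 0.13 without them. In WT cells it was at 0.0172 or below. Kdr, likewise not tested, was at 0.188 ± 0.0425 and 0.154 ± 0.0392 in KO cells with serine and glycine, and at 0.0396 ± 0.0382 and 0.209 ± 0.0755 without them. Pecam1 was at 0.057 or below in all groups, and these 3 genes were picked out after their values were seen. Of 15 stellate cell and fibroblast markers 2 passed, Pdgfra (1.13 and 1.92) and Ecm1 (7.63 and 14.8), and of 16 acinar and islet markers 0 passed. Ecm1 was at 17.2 in KO monocultures with serine and glycine and 52.1 in their cocultures, and at 16.8 and 77.4 without them. Cd68 in serine- and glycine-free KO cells was at 0.845 in monoculture and 3.8 in coculture, Cd14 at 2.19 and 4.59, Egfl7 at 0.277 and 0.64, and Pdgfra at 0.333 and 2.15.

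Adm, Egln3 and Selenbp1 were again among the largest rises in 2 further cocultures. WT cells without serine and glycine again had higher Adm (4.53 ± 0.11), Egln3 (4.17 ± 0.07) and Selenbp1 (3.53 ± 0.14). Also higher were the ductal keratin Krt19 (ENSMUSG00000020911, chromosome 11, 100140810 to 100148665; 3.30 ± 0.06) and Cyp2s1 (3.21 ± 0.06). Lower were Itih2 (−1.57 ± 0.11), Slco4a1 (−1.52 ± 0.08), Vnn1 (−1.45 ± 0.13), the checkpoint ligand Cd274 (−1.43 ± 0.11), Neurl3 (−1.32 ± 0.11) and Tmem158 (−1.30 ± 0.32). KO cells with serine and glycine had higher Selenbp1 (4.20 ± 0.14), Adm (3.99 ± 0.11), Egln3 (3.96 ± 0.07), Angptl4 (3.84 ± 0.08), the aquaporin Aqp8 (3.78 ± 0.11) and Pgf (3.44 ± 0.08). Their falls were led by Vnn1 (−2.37 ± 0.13), Abcc5 (−1.51 ± 0.05), Slco4a1 (−1.50 ± 0.08), Plscr2 (−1.27 ± 0.11), Dtx4 (−1.11 ± 0.05) and the macrophage growth factor Csf1 (−1.10 ± 0.10). Hypoxia genes rose in 27 of 29 cases in the serine- and glycine-free WT cells (median 1.67, camera adjusted p = 2.78e-40). In the KO cells with serine and glycine 26 rose (median 1.53, adjusted p = 2.49e-30). Cholesterol synthesis genes fell in 20 of 25 in the WT cells (21 adjusted over the list alone; median −0.52, adjusted p = 1.11e-11). In the KO cells 12 fell (16 adjusted over the list alone; median −0.25, adjusted p = 0.000481). Of 15 fatty acid synthesis genes 11 fell and 1 rose in the WT cells (11 and 2 adjusted over the list alone; median −0.39, adjusted p = 2.07e-05). In the KO cells 9 fell and 1 rose (median −0.39, adjusted p = 0.00168). Epithelial genes rose in 10 and fell in 3 of 15 in the WT cells (adjusted p = 0.000222) and rose in 11 and fell in 3 in the KO cells (adjusted p = 0.000553). Of 21 mesenchymal genes 9 rose and 2 fell in the WT cells (10 and 3 adjusted over the list alone; adjusted p = 0.00249). In the KO cells 14 rose and 5 fell (adjusted p = 0.000442). S phase genes rose in 24 and fell in 1 of 37 in serine- and glycine-free WT cells (27 and 1 adjusted over the list alone; median 0.40, adjusted p = 8.49e-10). Of 28 mitosis genes 26 rose there (27 adjusted over the list alone; median 0.42, adjusted p = 7e-10). In KO cells with serine and glycine S phase genes rose in 14 and fell in 2 (adjusted p = 0.0416, but adjusted p = 0.113 with an estimated correlation). Mitochondrially encoded genes fell in 6 of 13 (adjusted p = 0.0349, but adjusted p = 0.472 with an estimated correlation). Cholangiocyte markers rose in 5 and fell in 1 of 7 (adjusted p = 0.0295, but adjusted p = 0.0761 with an estimated correlation). ER chaperone genes rose in 8 of 20 in serine- and glycine-free WT cells (adjusted p = 0.0153, but adjusted p = 0.188 with an estimated correlation). Their median of 0.17 turned to −0.02 with quantile normalization (adjusted p = 0.989). The counts were 3386 in WT cells (1800 higher, 1586 lower) and 4824 in KO cells (2429 higher, 2395 lower). The share of higher calls was 53.2% in the WT cells, against 34.7% with scaling to each library total and 34.3% with voom, and 50.4% in the KO cells, against 37.4% and 37.9%. The second was 2840 with only its own groups in the fit. Replicate 1 of the KO monocultures in that comparison was the library that stood apart.

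In serine- and glycine-free KO cells, coculture raised hypoxia and cholesterol synthesis genes and lowered S phase genes. Bnip3 (ENSMUSG00000078566, chromosome 7, 138890836 to 138909519), a hypoxia-inducible mitophagy gene, rose from an FPKM of 0.834 ± 0.239 to 132 ± 9.25 (6.19 ± 0.07, adjusted p = 4.57e-22). Egln3 rose by 5.92 ± 0.07, Cyp2s1 by 5.18 ± 0.06, Scd2 by 4.79 ± 0.07 (from 13.5 ± 0.472 to 401 ± 32.2) and the pyruvate dehydrogenase kinase Pdk1 by 4.25 ± 0.08. The falls were led by Plagl1 (−3.33 ± 0.11), Ereg (−3.32 ± 0.13), Nr1d1 (−3.27 ± 0.10), the replication factor Pclaf (−2.99 ± 0.11), Rrm2 (−2.94 ± 0.12; 51.9 ± 4.46 to 5.89 ± 0.526) and Angptl8 (−2.7 ± 0.15). Hypoxia genes rose in 28 of 29 (median 2.69, camera adjusted p = 1.59e-16). Cholesterol synthesis genes rose in 24 of 25 (median 1.01, adjusted p = 1.4e-07). S phase genes fell in 35 of 37 (median −0.98, adjusted p = 9.99e-11). Mcm5 was at −2.30. ER chaperone genes rose in 17 and fell in 1 of 20 (17 and 2 adjusted over the list alone; adjusted p = 0.00017). NRF2 genes rose in 12 and fell in 6 of 23 (adjusted p = 0.0141). Gstm1 was at 3.55 and Slc7a11 at 2.85. Mesenchymal genes rose in 16 and fell in 4 of 21 (adjusted p = 0.00115). Itga5 was at 1.86. Called only at the preset correlation were rises of fatty acid synthesis genes (9 rose, 3 fell; adjusted p = 0.0764 with an estimated correlation) and ribosomal protein genes (26 of 37 rose; adjusted p = 0.191 with an estimated correlation). The same held for falls of mitosis genes (15 fell, 4 rose; adjusted p = 0.215 with an estimated correlation) and aminoacyl-tRNA synthetases (14 fell, 4 rose; adjusted p = 0.213 with an estimated correlation). Epithelial genes, 9 up and 5 down, did not pass (adjusted p = 0.151). Nor did serine and one-carbon enzymes, 8 up and 12 down with Aldh1l1 at 1.56 (adjusted p = 0.607). In all 8594 genes were called, 4221 higher and 4373 lower. Of these, 1299 and 1030 changed at least 2-fold.

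Interferon response, p53 target, NF-kB, serine and one-carbon, and ATF4 lists did not pass in any of the 17 comparisons, although members did. On withdrawal in KO monocultures most members of each were called, both up and down, which a test of one-way shifts can miss. Interferon response genes fell in 4 and rose in 1 of 9 in KO against WT monocultures with serine and glycine, with Bst2 at −1.69 (adjusted p = 0.38). In KO monocultures on withdrawal 6 fell and 1 rose, with B2m at −1.58 (adjusted p = 0.132). In WT coculture with serine and glycine 5 fell and 2 rose, with H2-K1 at 1.01 (adjusted p = 0.239). Among p53 targets 8 rose and 6 fell of 22 on withdrawal in KO monocultures, with the cell cycle inhibitor Cdkn1a at 1.12 (adjusted p = 0.854). In WT coculture with serine and glycine 4 rose and 4 fell (4 and 5 adjusted over the list alone). Cdkn1a was at 2.39 (adjusted p = 0.894). NF-kB and inflammatory genes rose in 7 and fell in 7 of 18 on withdrawal in KO monocultures, with Il33 at 2.21 and Cxcl5 at −1.88 (adjusted p = 0.802). In WT coculture with serine and glycine 4 rose and 7 fell, with Il33 at 2.32, Lif at 1.90 and Ccl20 at −1.82 (adjusted p = 0.986). Serine and one-carbon enzymes in WT coculture with serine and glycine rose in 6 and fell in 7 (7 and 9 adjusted over the list alone). Mthfd1l was at 1.17 and Gldc at 0.92 (adjusted p = 0.897). ATF4 genes rose in 6 and fell in 7 of 30 (adjusted p = 0.767).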

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

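The tests of hepatocyte RNA in the libraries and of chromosome-wide differences between the lines, and the splits after removal of other effects, were chosen only after the results they bear on had been seen; the other tests in this part were written down first. The interactions stood out when the difference between effects was tested, and all but that in WT cells share one group. The 3 patterns weighed at the end were picked for follow-up and are not interactions.

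In monoculture the response to serine and glycine withdrawal differed between KO and WT cells for 7385 genes. It was higher in KO cells for Sprr1a (5.92), Dynap (5.31), Nr1d1 (4.92), Rrm2 (4.76) and Phgdh (0.74), and lower for Scd2 (−5.55), Lgals4 (−5.25), Slco4a1 (−4.39) and Gstm1 (−4.24). The list medians of the difference were 1.32 for S phase, 1.45 for mitosis, −1.61 for cholesterol synthesis, −0.98 for fatty acid synthesis, −1.13 for hypoxia and glycolysis, −0.75 for ER chaperones and −0.34 for NRF2 and glutathione genes. Plain splits of the libraries turn the effects of genotype, medium and coculture into calls of an interaction, so they decide nothing about chance, and for each of the 5 interactions the splits were also drawn after all other effects had been removed. Here 1 of 100 plain splits of the 12 libraries, the real one, called as many genes, with 7311 in the highest other. With the other effects removed it was again 1 of 100, the smallest share these splits can give, with 5582 genes in the highest other. Chance differences between cultures cannot be judged this way, because the replicates may be technical.

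In KO cells the response differed between coculture and monoculture for 6962 genes, with Scd2 (4.68), Vnn1 (4.48) and Gstm1 (4.46) higher in coculture and Sprr1a (−4.69), Nr1d1 (−4.03), Ereg (−3.52), Rrm2 (−3.49) and Phgdh (−0.84) lower. Medians were −1.13 for S phase, 1.05 for cholesterol synthesis, 0.75 for fatty acid synthesis, 0.84 for hypoxia and glycolysis, 0.66 for ER chaperones and 0.41 for NRF2 genes. As many genes were called in 2 of 100 plain splits, the highest other calling 7660, more than the real count. These splits turn the other effects into calls, so this decides nothing. With the other effects removed only the real split, 1 of 100, called as many, the highest other calling 4786, with the same limit. In WT cells 201 genes differed, with Rrm2 (1.02), Ect2 (0.83), Gmnn (0.77) and Mcm3 (0.67) higher in coculture and Apoe (−1.28), Plppr3 (−0.88), Leng8 (−0.85) and Fat1 (−0.75) lower. Medians were 0.32 for S phase, 0.46 for mitosis and −0.12 for fatty acid synthesis genes. As many genes were called in 16 of 100 plain splits, and the highest other called 1921, several times the real count, which again decides nothing. With the other effects removed only the real split, 1 of 100, called as many, the highest other calling 1, again with that limit.

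Without serine and glycine the effect of coculture differed between KO and WT cells for 7343 genes. Higher in KO cells were Scd2 (4.63), Slco4a1 (4.44), Gstm1 (4.18) and Lrrc66 (4.08), and lower were Rrm2 (−4.82), Ereg (−4.20), Pclaf (−3.95), Dynap (−3.94) and Phgdh (−0.67). Medians were −1.37 for S phase, −0.99 for mitosis, 1.39 for cholesterol synthesis, 0.70 for fatty acid synthesis and 0.44 for NRF2 genes. The real split was the only 1 of 100 plain splits with as many genes, the highest other calling 5252. It was the only 1 of 100 with the other effects removed too, the highest other calling 4630, with the same limit. The interaction of all 3 factors called 5605 genes, among them Scd2 (4.93), Vnn1 (4.62), Gstm1 (4.52) and Slco4a1 (4.36) with positive and Sprr1a (−4.69), Rrm2 (−4.51), Pclaf (−3.88), Nr1d1 (−3.87) and Phgdh (−1.05) with negative differences. Medians were −1.50 for S phase, −1 for mitosis, 1.18 for cholesterol synthesis, 0.79 for fatty acid synthesis, 0.89 for hypoxia and glycolysis, 0.70 for ER chaperones and 0.53 for NRF2 genes. Again 1 of 100 plain splits of the 24 libraries, the real one, called as many, the highest other calling 107. With the other effects removed it was 1 of 100, the highest other calling 3445, with the same limit.

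For comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05, and the real split was the 1 with the most calls in each. KO against WT cells gave 5145 genes in monoculture with serine and glycine (highest other split 0), 8880 without (0), 5291 in coculture with (2) and 6470 without (2). Withdrawal gave 196 in WT monoculture (highest other 1), 8534 in KO monoculture (2), 89 in WT coculture (1) and 3607 in KO coculture (0). Coculture gave 3763 in WT cells with serine and glycine (highest other 0), 4824 in KO cells with (1), 3386 in WT cells without (1) and 8594 in KO cells without (1). In KO monocultures same-numbered libraries deviated together, though no label pairs them. The other splits that part all same-numbered libraries are among those that called at most 2 genes. Such splits mix the media, which puts the effect of medium into the spread, so their low counts decide nothing about a pairing.

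On the first component within groups, which held 30.8% of the variance within groups, replicate 1 of KO monocultures with serine and glycine lay at 31 and replicates 2 and 3 at −17.4 and −13.5, and replicates 1 and 2 of serine- and glycine-free KO cocultures lay at opposite ends (−19.7 and 20.1, with replicate 3 at −0.4). Lower depth is argued against, since after thinning every library to 15740081 reads that component still held 29.8%, a ratio of 0.97. GC content bias between libraries is a candidate explanation, because the deviations of the first and of these cocultures' replicate 2 followed gene GC content (absolute Spearman rho of at least 0.56, across genes, and 0.57 for their replicate 1) and correction for GC content and length lowered the share to 20.5%. That correction removed 14% of the variance within groups, so it leaves most of it open. Deviations of the serine- and glycine-free KO monocultures followed GC content too (Spearman rho −0.6, 0.51 and 0.38 for replicates 1, 2 and 3). On the first component within groups they lay at 10.8, −6.8 and −4. No biological explanation was tested, as the labels give these libraries no condition of their own.

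Hypoxia and glycolysis genes were higher in all 4 coculture comparisons. Hepatocyte RNA in the libraries is argued against, since the highest FPKM of Alb, Apoa1, Ttr, Fgb and Serpina1b in a coculture library was 0.183, whereas the median list member rose by 37.7 to 44.8 FPKM. GC content and length bias is argued against as the whole cause, since after correction the medians of 1.55, 1.45, 1.59 and 2.60 were at least 0.95 times those before. A response of the cancer cells to coculture may account for it, as a hypothesis found and tested on the same data. Oxygen, cell density and medium composition in the dishes were not measured in these data and stay open.

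Differences between KO and WT cells recurred in every condition, with 1914 genes called with one sign in all 4 comparisons. GC content and length bias is argued against, since after correction a share of 0.91 of these genes stayed so. Chromosome-wide differences between the KO and WT lines may contribute, because the chromosome medians of the KO against WT change were alike in monoculture and coculture with serine and glycine (Spearman rho 0.93 over 20 chromosomes, which are not independent replicates). In monoculture the chromosome explained 8.24% of the variance of the change, against at most 0.4% in 10000 shuffles (permutation p = 1e-04, the smallest they can give), with medians from −0.35 for the X chromosome to 0.21 for chromosome 15. Loss of Phgdh itself and other differences between the lines, such as those between clones, were not tested apart and stay open.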

How the results depend on the processing

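The alternatives chosen after seeing the data are named above. Of the 17 counts of called genes, 11 stayed within 1.5 times their reported value in every alternative, and all 17 did with median-of-ratios scaling, quantile normalization, voom, no filter, the replicate block, library totals and protein-coding genes alone. A fit to only the groups of the contrast has fewer libraries and takes the spread from those groups alone. KO against WT cells in monoculture with serine and glycine then gave 3165 genes and coculture in KO cells with serine and glycine 2840. Withdrawal gave 4 in WT coculture and 1820 in KO coculture. Higher than reported were withdrawal in WT monoculture (302) and the interaction of medium and coculture in WT cells (552). Median gene SDs on the log2 scale were 0.071 to 0.085 in WT groups. They were 0.067 in KO cocultures with serine and glycine and 0.106 to 0.169 in the other KO groups. The spread shared by all groups in the main fit can thus be too wide for some groups and too narrow for others. Without replicate 1 of KO monocultures with serine and glycine and replicate 2 of serine- and glycine-free KO cocultures the WT counts were 518 for withdrawal in monoculture, 241 in coculture and 543 for their interaction. Without that replicate 1 and replicate 1 of the same cocultures they were 525, 232 and 546, withdrawal in KO coculture gave 5763 genes and the KO slope was 0.187. With the correction for GC content and length withdrawal in WT coculture gave 219; the cause was not tested. With a pseudocount of 0.1 withdrawal in WT coculture gave 59 genes, and the WT slope turned to 0.018. With the replicate block and the correction for GC content and length withdrawal gave 130 genes in WT monoculture and 198 in WT coculture, and the WT slope was −0.271; the cause was not tested.

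Leaving out single libraries gave ranges of 4434 to 5138, 8506 to 8579, 4649 to 4768 and 5757 to 6603 genes for KO against WT cells (monoculture with and without serine and glycine, then coculture with and without). Withdrawal gave 62 to 140 in WT monoculture (62 without replicate 3 of the serine- and glycine-free libraries), 8120 to 8640 in KO monoculture, 37 to 50 in WT coculture (37 without replicate 1 of the libraries with serine and glycine, and every library left out lowered it by over 1.5 times) and 2152 to 4619 in KO coculture (without replicates 2 and 1 of the serine- and glycine-free libraries). Coculture gave 3113 to 3216 in WT and 4102 to 4976 in KO cells with serine and glycine, and 2715 to 2870 in WT and 8162 to 8380 in KO cells without. The interactions gave 7026 to 7758 (genotype and medium), 6591 to 7208 (medium and coculture, KO), 100 to 195 (medium and coculture, WT; 100 without replicate 1 of the serine- and glycine-free cocultures), 6982 to 7298 (genotype and coculture) and 5309 to 6106 (all 3 factors). The slope ran from 0.114 to 0.166 in KO and from −0.27 (without replicate 1 of the monocultures with serine and glycine) to −0.127 in WT cells.

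Among 1235 results for named genes, 158 changed their side of the threshold or direction under at least 1 alternative, and among 131 called lists 56 did, 52 of them with an estimated correlation. Directions reversed, with a call in one of the fits, for Sars in coculture of KO cells with serine and glycine (−0.04 with quantile normalization), Phgdh in coculture of serine- and glycine-free KO cells (−0.41 with quantile normalization) and Loxl2 in the interaction of genotype and coculture (2.73 with voom). Phgdh in KO against WT cells in serine- and glycine-free monoculture, called in neither, went from −0.21 to 0.19 with quantile normalization; the cause was not tested. The share of calls that were higher fell with library totals from 52.3% to 35.8% for coculture in WT cells with serine and glycine, from 50.4% to 37.4% in KO cells with them and from 53.2% to 34.7% in WT cells without. With the correction for GC content and length it went from 84.2% to 71.3% for withdrawal in WT monoculture and from 25.4% to 38.6% for the interaction in WT cells. The replicate block gave 147 genes for withdrawal in WT monoculture, 75 in WT coculture and 3342 in KO coculture, and ended the call of 11 named genes, among them Fosb in WT monoculture (adjusted p = 0.0793). The labels give such libraries only a shared number. Outside the comparison of medium in KO monocultures, same-numbered libraries did not deviate together. In serine- and glycine-free KO cells their correlations between cultures were −0.34, −0.26 and −0.01. Changes of 1.5-fold or less were often missed in the simulated reads. How often this holds in the real data was not tested.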

Other observations

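The gene sets in this part, and the 15 camera tests on them (3 sets by 5 comparisons, with Benjamini-Hochberg adjustment over these), were chosen after the data had been seen. The medians of the sets kept their sign with median-of-ratios scaling, quantile normalization and scaling to each library total. Ligands of the epidermal growth factor (EGF) family, 5 tested ligands of the EGF receptor and Nrg1, a ligand of ErbB3 and ErbB4, moved apart on serine and glycine withdrawal in KO monocultures. Ereg went from an FPKM of 6.42 ± 1.6 to 156 ± 14.4, Areg from 78.6 ± 24.7 to 777 ± 69.9 and Btc from 5.35 ± 1.05 to 37.7 ± 5.06. Hbegf went from 29.1 ± 1.05 to 20.2 ± 1.24 and Tgfa from 9.2 ± 0.614 to 4.68 ± 0.074. Of 6 tested ligands 3 rose and 2 fell (median 1.35, adjusted p = 0.309), Nrg1 not passing (0.08, adjusted p = 0.364), and the set was not called. In coculture of WT cells with serine and glycine 5 of the 6 rose and 0 fell (median 0.76, adjusted p = 0.000134, and adjusted p = 0.0268 with an estimated correlation). Coculture of serine- and glycine-free KO cells raised 2 and lowered 4, among them Ereg (−3.32) and Areg (−1.95), and the set was not called (median −0.51, adjusted p = 0.533). Withdrawal in KO coculture raised 3 and lowered 0 (median 0.51, adjusted p = 0.00165), a call that was lost with an estimated correlation (adjusted p = 0.0573). The difference between the responses to withdrawal of KO cells in coculture and monoculture was not called for the set (2 higher, 3 lower, median −0.72, adjusted p = 0.467). Of the receptors, Erbb2 had group means of 5.35 to 12.1, and Egfr of at most 0.0779, Erbb3 of at most 0.659 and Erbb4 of 0.

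Ribosome biogenesis genes rose in KO monocultures on withdrawal, where the cytosolic ribosomal protein list fell, the latter a call that was lost with an estimated correlation (adjusted p = 0.0839). Of 28 biogenesis genes 21 rose and 4 fell (median 0.83, adjusted p = 0.000204, and adjusted p = 0.0268 with an estimated correlation), among them Znhit6 (FPKM 12.3 ± 0.459 to 71 ± 1.28) and Bop1 (18.5 ± 2.56 to 62.9 ± 7.04). The abundant nucleolar genes Npm1 (883 to 352, log2 change −1.33) and Ncl (186 to 111, −0.74) were among those that fell. In serine- and glycine-free KO cells coculture lowered 26 of the 28 and raised 1, Npm1 (median −1.52, adjusted p = 3.84e-10, and adjusted p = 0.00298 with an estimated correlation). In WT cells with serine and glycine it lowered 13 and raised 0 (median −0.22, adjusted p = 0.000204, and adjusted p = 0.0268 with an estimated correlation). Withdrawal in KO coculture lowered 7 and raised 2 (median −0.13, adjusted p = 0.043), a call that was lost with an estimated correlation (adjusted p = 0.178). The response to withdrawal in KO cells was lower in coculture than in monoculture for this set when the difference was tested (median −0.82, adjusted p = 1.87e-06, and adjusted p = 0.0129 with an estimated correlation).

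Circadian clock genes changed unevenly. In KO monocultures 9 of 14 rose and 2 fell on withdrawal (median 0.59, adjusted p = 0.0274, and adjusted p = 0.045 with an estimated correlation). In KO coculture 3 rose and 5 fell, and the set was not called (median −0.19, adjusted p = 0.121). The difference between both responses was called (1 higher and 11 lower in coculture, median −0.79, adjusted p = 0.00165, and adjusted p = 0.0129 with an estimated correlation). Nr1d1 went, in KO monocultures, from an FPKM of 3.16 ± 0.199 to 140 ± 14.8, while its close relative Nr1d2 was at 18.5 ± 2.66 and 17 ± 2.65. The effect of coculture went opposite ways in 2 comparisons. In WT cells with serine and glycine coculture raised 7 of the 14 and lowered 2 (median 0.35, adjusted p = 0.00165, and adjusted p = 0.0129 with an estimated correlation). In serine- and glycine-free KO cells it lowered 11 and raised 2 (median −0.80, adjusted p = 0.0134, and adjusted p = 0.0276 with an estimated correlation).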
